A study of Homo sapiens with 10 samples.

How the data were processed

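RNA in 10 libraries from human retinal microvascular endothelial cells was compared, 5 treated for 6 hours with 1% DMSO and 5 with APX2009. Per the labels' protocols, total RNA was extracted with a QIAGEN kit and libraries were made with the KAPA mRNA HyperPrep kit, which captures polyadenylated RNA. The deposited table holds raw counts of reads per gene, with no normalisation, for 66738 genes, of which 6135 lie on alternative or unplaced sequences. Per the submitters' processing notes, bcl2fastq, STAR 2.7.2a, featureCounts, Subread 1.6.5 and edgeR were used with hg38. The annotation release and the settings for strand and multiply mapped reads are not given in the sources used here. The values show that counting used strand and mostly did not count a read for several genes overlapping at its place on the same strand. Of 187 nuclear genes whose exons lay wholly under expressed exons of the opposite strand 15.5% had no count, against 94.2% of 291 such genes on the same strand. How reads that map to several places were counted was not tested. Counts of genes that overlap another on the same strand, or that have near-identical copies, are therefore uncertain.

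Groups and replicate numbers came from the sample titles, and columns were matched to samples by name. All columns were used, and every row named a gene. No pair of libraries was identical, and within groups the chi-square per degree of freedom between libraries was 4.61 to 75.0, above sampling noise. Gene coordinates and types are those of the deposited table, 1-based. Where the table gave a clone name and the reference table of names gave a symbol for its identifier, the symbol was used (486 genes). XIST and Y-linked genes were tested but are neither named nor plotted.

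Genes were kept with edgeR's filterByExpr at its defaults (minimum count 10, minimum total 15), scaled with TMM factors and tested with the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit with robust dispersion, model of group alone, two-sided) in R 4.3.3. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size over the square root of F. CPM values are per 1000000 counts with the TMM factors applied. The maxima given for markers of other cell types are CPM of the library total, without those factors. Gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, two-sided) for 35 of 40 lists that had at least 5 tested genes, adjusted over those lists. All 945 list entries matched a gene in the table. Beside it stand camera with an estimated correlation, which called 4 lists (among them AP-1 and immediate early genes, aryl hydrocarbon receptor targets and apoptosis regulators), and fry, which asks whether a list's genes move on balance one way and called 21. The lists share members, JUN being in both the AP-1 and the Ref-1 list for example, so they are not independent. Values per library were compared with two-sided exact permutation tests, adjusted over 8 measures.

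The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule took genes with a symbol, leaving out XIST, TSIX and Y-linked genes. It took 9 genes whatever their result, among them APEX1, HIF1A, NFKB1, RELA, STAT3, NFE2L2, JUN and FOS; the remaining gene and 1 called gene list that goes with it are counted in the totals but not reported here. It also took the 12 largest increases and the 12 largest decreases among called genes with at least 5 CPM in the higher group and no overlap between groups, and in each list of 5 or more tested genes the 3 members with the smallest p. Lists of other cell types are given by their members' counts and their most abundant members. PTPRC, PDGFRB and AQP4 were added as examples of near-absent markers, and CORO1A and GLUL as the members that changed, and TAGLN as one that changed with the replicate block, after their values were seen.

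The replicate numbers 1 to 5 recur in both groups. Libraries with the same number deviated from their group means together, with correlations of 0.139 to 0.495 in all 5 pairs, above the minimum of 0.1 set for pairing, so a fit with the number as a block is printed where it changes a call. Between libraries with different numbers the correlations were -0.456 to 0.373, so some exceeded those of same-numbered libraries. The pairing is inferred from the data, as the labels do not say what a number shares.

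The tests were tested on simulated data with known answers, made for APX2009 against DMSO from the real means, dispersions and library sizes. Over 14628 genes the test called 64.2% of genes changed 1.5-fold, 97.0% of those changed 2-fold and 100% of those changed 4-fold, and 5.43% of its calls were false. Only 67, 67 and 66 genes were changed by these folds, while 31.5% of tested genes were called in the real data. With so few changed genes the adjustment is stricter, so these shares need not hold for the real comparison. In a second simulation the 1 raised list was called, and of 34 unchanged lists camera called 0 and fry 1. Simulated genes vary independently, unlike real ones, so this does not show how often camera calls an unchanged list in real data. In 99 other splits of the real libraries, 98 of them with 0 genes called by edgeR, camera called a median of 7 lists. Each of those splits keeps part of the treatment difference, so its calls need not be false. The biological coefficient of variation was 0.145. The alternatives were other scaling factors, low-count filters (none, or at least 5 CPM in 5 libraries), DESeq2 1.42.0, limma-voom, a fit without robust dispersion, the replicate block, stricter thresholds, leaving out mitochondrial genes and leaving out each library in turn.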

Results

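RNA was sequenced from human retinal microvascular endothelial cells (HRMECs), the cells that line the small vessels of the retina and that the labels list as a cell line. The cells were kept in normoxia for 6 hours with either 1% DMSO or APX2009, a small molecule that inhibits the redox function of Ref-1. The labels do not say whether the APX2009 cells also received DMSO. If they did not, effects of the compound and of DMSO cannot be told apart. Ref-1 is the product of APEX1, a base excision repair enzyme that also changes the redox state of several transcription factors. The labels write the dose as 10 mM; micromolar doses are usual for such compounds, so the unit is in doubt and is printed only as they give it. Each group had 5 libraries. The total count over genes was 32908759 to 36959094 per library for DMSO and 27932423 to 36838595 for APX2009, and the difference between the groups did not pass the test (two-sided exact permutation p = 0.206, n = 5 per group). The labels do not say whether the replicates were separate cultures or donors, so p-values measure only the spread between these samples, which may be technical.

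The comparison of APX2009 with DMSO asked which transcripts changed after 6 hours with the compound. The stress and growth factor response gene ATF3 rose the most, from 4.68 ± 0.551 CPM (counts scaled to 1000000 per library, mean ± SD, n = 5) with DMSO to 129 ± 26.6 CPM with APX2009, a 27.6-fold increase. The transcription factors KLF4 and EGR1 rose 12.2-fold and 9.22-fold, the prostaglandin synthase PTGS2 10.7-fold, the chemokine CXCL8 7.26-fold, the chemokine receptor CXCR4 6.32-fold, and the long noncoding RNA NEAT1, a scaffold of nuclear paraspeckles, 6.59-fold. The thrombin receptor F2RL3 rose 6.78-fold, the insulin receptor substrate IRS2 5.01-fold and the growth factor signalling inhibitor SPRY2 4.87-fold. In the other direction, CYP26B1, an enzyme that breaks down retinoic acid, was 7.83-fold lower, LINC00641 5.11-fold, the RNA methyltransferase BCDIN3D 5.07-fold, FAM78A 4.29-fold and the zinc finger gene ZNF552 4.52-fold. HSD17B1-AS1, which lies antisense to another gene, was 4.84-fold lower; the use of strand in counting is not stated, but the counts show it. The remaining genes among the 12 with the largest decrease were mitochondrial and are described further on. All of these genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with adjusted p between 1.34e-10 for ATF3 and 5.23e-05 for NEAT1, and the 5 libraries of one group did not overlap those of the other for any of them.

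**Figure D1:**
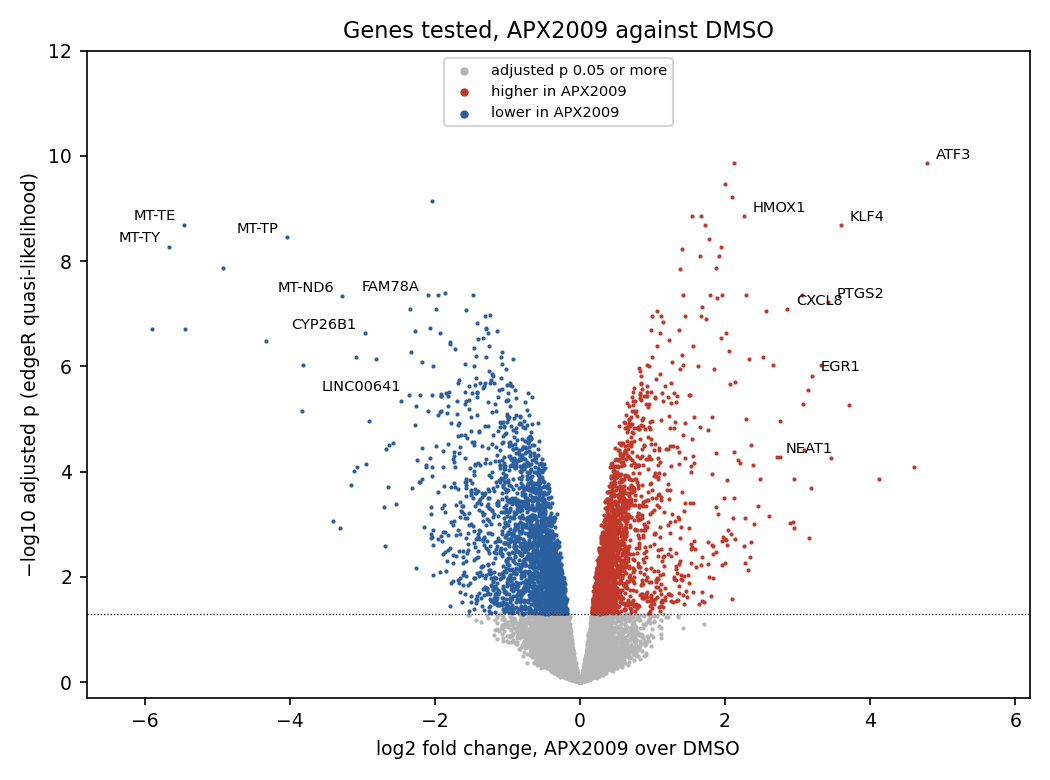
Each point is a tested gene, with its log2 fold change (APX2009 over DMSO) on the x axis and the −log10 of edgeR's adjusted p on the y axis; red and blue points passed an adjusted p of 0.05 (dotted line), and XIST and Y-linked genes are not drawn. ATF3 stands farthest to the right at 4.79, and a few mitochondrial genes stand farthest to the left, among them MT-TY at -5.66.

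In all, 4671 of 14852 tested genes (31.5%) had an adjusted p under 0.05 in edgeR's quasi-likelihood test. Of these, 2158 were higher and 2513 lower with APX2009, and 830 changed at least 2-fold, 282 up and 548 down. Protein-coding genes gave 1973 higher and 2187 lower of 11933 tested, and long noncoding RNA genes 111 higher and 245 lower of 1496. The first principal component, with 44.5% of the variance, separated the groups. The balance of directions depended on the scaling: 46.2% of the called genes were higher with the factors used here, 50.5% with median-ratio factors, 51.2% with DESeq2, 33.3% with upper-quartile factors and 26.9% with library size alone. The last 2 moved the median log2 fold change of all genes from -0.01 to -0.09 and -0.11. With the replicate number as a block, 6509 genes were called, 3284 of them higher.

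The group that rose most was the list of AP-1 and immediate early genes, fast-responding transcription factors, phosphatases and their targets. Of 30 tested members 24 rose, 1 fell and 5 did not pass (26 and 1 when adjusted over the list alone), with a median log2 fold change of 0.93. Besides ATF3, KLF6 rose 3.18-fold from 170 ± 12.2 to 542 ± 28.5 CPM, and the MAP kinase phosphatase DUSP1 rose 3.89-fold from 32.7 ± 3.45 to 127 ± 21.7 CPM. JUN, the main AP-1 subunit, rose 3.69-fold from 123 ± 14.8 to 452 ± 71.4 CPM (log2 fold change 1.88 ± 0.11 SE, edgeR adjusted p = 5.07e-08). FOS, its partner, was rare but rose 2.89-fold, from 0.475 ± 0.0968 to 1.39 ± 0.666 CPM (edgeR adjusted p = 0.00237). The list was called by camera (adjusted p = 7.05e-26) and also with an estimated correlation (adjusted p = 0.0255). ATF3 (ENSG00000162772.17) lies on chromosome 1 from 212565334 to 212620777 (+ strand, hg38), and JUN (ENSG00000177606.6) on chromosome 1 from 58780788 to 58784327 (− strand).

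APEX1 itself, the gene of the drug's target, was 254 ± 14.3 CPM with DMSO and 267 ± 14.5 CPM with APX2009 (log2 fold change 0.07 ± 0.06 SE, edgeR adjusted p = 0.412). It lies on chromosome 14 from 20455191 to 20457772 (+ strand). Among 15 tested members of the list of Ref-1 and the transcription factors it is reported to regulate, 8 rose and 1 fell (8 and 2 adjusted over the list alone), and the list was called (camera adjusted p = 0.000474), though not with an estimated correlation (adjusted p = 0.0695). JUN, EGR1 and NFE2L2 had the smallest p. NFE2L2, which encodes the oxidative stress regulator NRF2, rose 1.85-fold from 95.3 ± 9.97 to 176 ± 14.3 CPM (edgeR adjusted p = 3.66e-06). NFKB1 rose 1.26-fold (edgeR adjusted p = 0.0125), a call that library size alone ended (adjusted p = 0.0652). RELA, the other main NF-kB subunit, had a log2 fold change of -0.03 (edgeR adjusted p = 0.826). STAT3 had a log2 fold change of 0.16 and an edgeR adjusted p of 0.0470. That call ended with upper-quartile factors (adjusted p = 0.225), with library size alone (0.461), without a low-count filter (0.196), with the stricter filter (0.0515), and on leaving out any 1 library other than DMSO replicate 5 or APX2009 replicate 1 (0.0575 to 0.128). HIF1A, the oxygen-responsive factor, was 212 ± 55.5 CPM with DMSO and 258 ± 36.0 CPM with APX2009 and did not pass (edgeR adjusted p = 0.171), but passed with the replicate number as a block (adjusted p = 0.00533) and without DMSO replicate 5 (adjusted p = 0.0363).

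**Figure D2:**
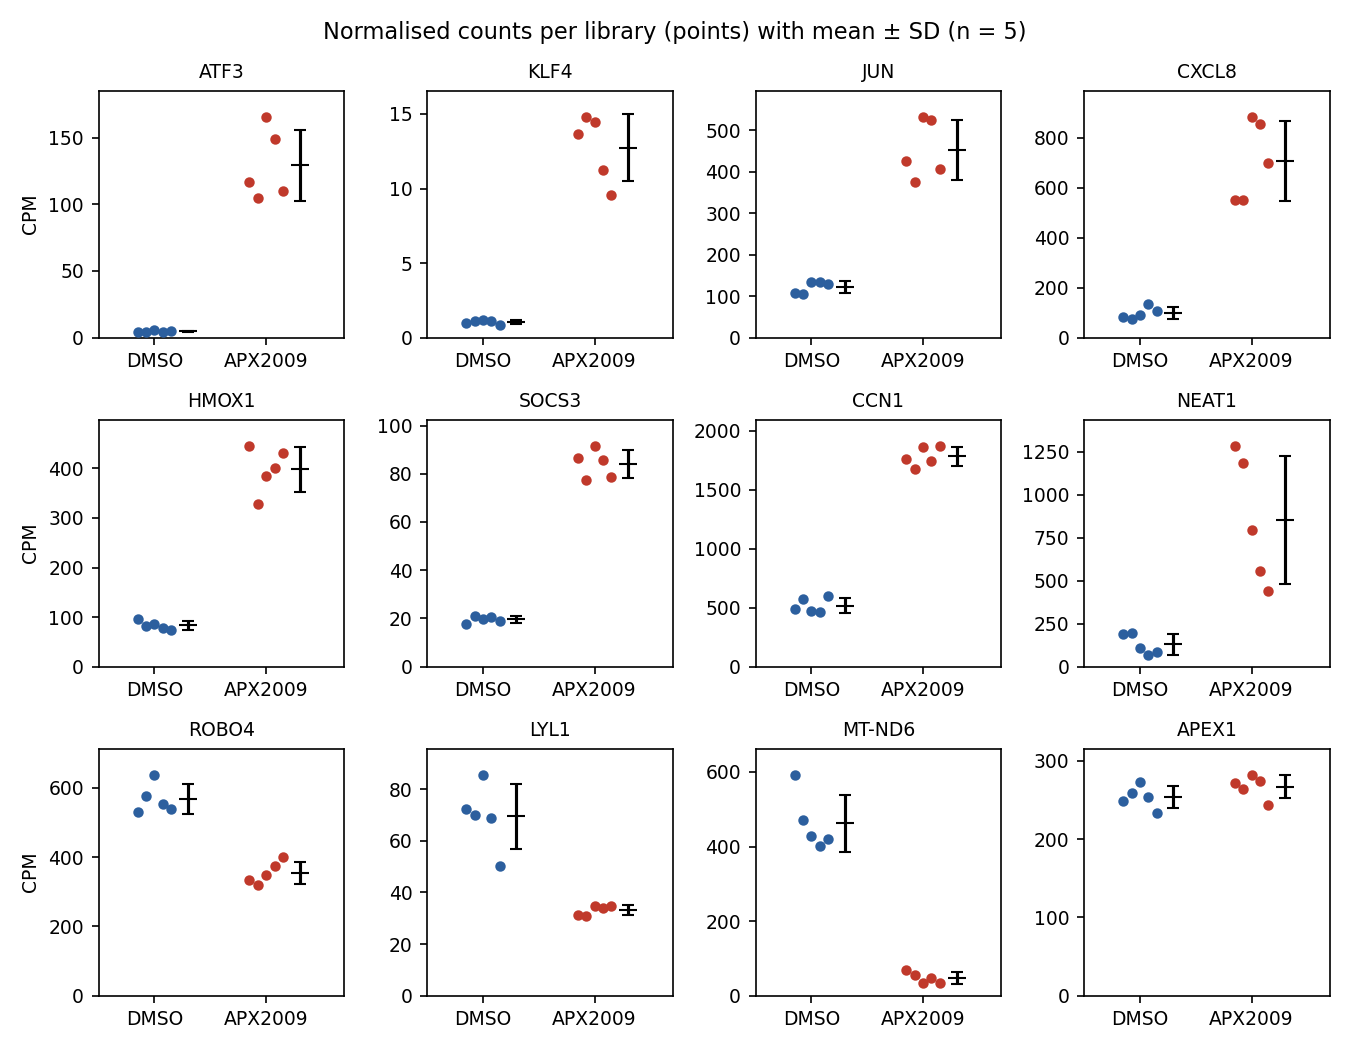
Each panel gives 1 gene's normalised count in CPM (linear y axis from 0) in each of the 5 DMSO (blue) and 5 APX2009 (red) libraries, with the mean and SD beside the points. ATF3, KLF4, JUN, CXCL8, HMOX1, SOCS3, CCN1 and NEAT1 are higher in every APX2009 library, ROBO4, LYL1 and MT-ND6 are lower in every one, and the APEX1 values overlap.

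Of 38 tested NRF2 targets 16 rose and 5 fell (17 and 6 adjusted over the list alone). HMOX1, which breaks down heme, rose 4.79-fold from 83.1 ± 8.18 to 398 ± 45.3 CPM, the NRF2 partner MAFG 1.99-fold and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.92-fold. Of 6 tested aryl hydrocarbon receptor targets 4 rose and 0 fell (the same numbers adjusted over the list alone), led by TIPARP, 3.86-fold. Of 24 tested apoptosis regulators 13 rose and 2 fell (14 and 3 adjusted over the list alone). They included both the proapoptotic PMAIP1, 2.93-fold, and the antiapoptotic MCL1, 1.81-fold, and BIRC3, 8.83-fold from 0.165 ± 0.0138 CPM. All 3 lists were called as higher by camera, with adjusted p of 0.000175 for NRF2, 0.000440 for the aryl hydrocarbon receptor and 0.000474 for apoptosis. With an estimated correlation the adjusted p was 0.0319 for both of the last lists, and the NRF2 list lost its call (adjusted p = 0.136).

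Of 24 tested NF-kB targets 12 rose and 3 fell (14 and 5 adjusted over the list alone). NFKBIZ, a nuclear regulator of NF-kB, rose 8.36-fold from 2.62 ± 0.521 to 21.9 ± 5.09 CPM, and F3, the tissue factor that starts coagulation, 10.0-fold from 0.379 ± 0.165 to 3.86 ± 0.848 CPM. CXCL8 had 97.6 ± 23.8 CPM with DMSO and 708 ± 160 CPM with APX2009. The list was called as higher (camera adjusted p = 0.000175), but not with an estimated correlation (adjusted p = 0.0670) nor among genes of at least 5 CPM (adjusted p = 0.0579). Of 22 tested YAP and TEAD targets 12 rose and 3 fell (13 and 3 adjusted over the list alone). The matricellular gene CCN1 rose 3.44-fold from 518 ± 62.6 to 1784 ± 82.8 CPM and GADD45B 2.95-fold. The camera adjusted p was 1.40e-06, and 0.136 with an estimated correlation. Of 13 tested members of the list of shear stress KLF2 and KLF4 targets 5 rose and 0 fell, over all genes and adjusted over the list alone. Besides KLF4 they included the lipid phosphatase PLPP3, 2.47-fold, and ANGPT2, 1.68-fold, a vessel-destabilising ligand that KLF2 is known to repress, so the list does not hold induced genes alone. It had a camera adjusted p of 0.00251, and of 0.0517 with an estimated correlation.

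Endothelial identity was the 1 list called as lower. Of 29 tested members 12 fell and 1 rose (13 and 1 adjusted over the list alone), with a median log2 fold change of -0.25. The haematopoietic and endothelial transcription factors LYL1 and TAL1 were 2.09-fold and 1.73-fold lower, and the endothelial guidance receptor ROBO4 had a log2 fold change of -0.68, from 568 ± 42.6 CPM with DMSO to 355 ± 31.9 CPM with APX2009. The camera adjusted p was 0.00790, and 0.210 with an estimated correlation. Of 26 tested angiogenic sprouting genes 8 rose and 4 fell, over all genes and adjusted over the list alone. INHBA, an activin subunit, rose 2.92-fold and the lymphangiogenic factor VEGFC 1.55-fold, beside CXCR4. Of 20 tested STAT3 targets 6 rose and 2 fell (6 and 4 adjusted over the list alone), with the feedback inhibitor SOCS3 up 4.27-fold from 19.7 ± 1.36 to 84.0 ± 5.91 CPM and the kinase PIM1 3.66-fold. In both lists the median log2 fold change was -0.04 while the mean was above 0 (0.21 and 0.09) and camera called the list as higher (adjusted p of 0.0314 and 0.0152). Neither was called with an estimated correlation (adjusted p of 0.440 and 0.0695). The sprouting list also lost its call among genes of at least 5 CPM (adjusted p = 0.0773), without DMSO replicate 3 (0.0623) and without APX2009 replicate 5 (0.101).

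The other lists called as higher moved little. Of 45 tested ribosomal protein genes 10 rose and 0 fell, over all genes and adjusted over the list alone, with a median log2 fold change of 0.18. RPL22 rose 1.21-fold (edgeR adjusted p = 0.00437). The camera adjusted p of 0.00251 became 0.734 with an estimated correlation, 0.118 with fry and 0.0573 without DMSO replicate 5. Of 43 tested nuclear genes of oxidative phosphorylation 8 rose and 0 fell (3 and 0 adjusted over the list alone), among them SDHD, 1.33-fold. The camera adjusted p of 0.0309 became 0.734 with an estimated correlation, 0.157 with fry, 0.0977 with upper-quartile factors, 0.0813 with library size alone and 0.209 among genes of at least 5 CPM. It became 0.0615 without DMSO replicate 4, 0.203 without DMSO replicate 5 and 0.0955 without APX2009 replicate 1. Of 26 tested autophagy and lysosome genes 10 rose and 2 fell, over all genes and adjusted over the list alone. The autophagosome genes GABARAPL1 and MAP1LC3B rose 2.42-fold and 1.40-fold. The camera adjusted p of 0.0392 became 0.345 with an estimated correlation, 0.0767 with upper-quartile factors, 0.0813 with library size alone, 0.0587 without DMSO replicate 4 and 0.101 without APX2009 replicate 5. Ribosomal protein genes have many near-identical pseudogenes, so their counts are uncertain where the counting could split reads.

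**Figure D3:**
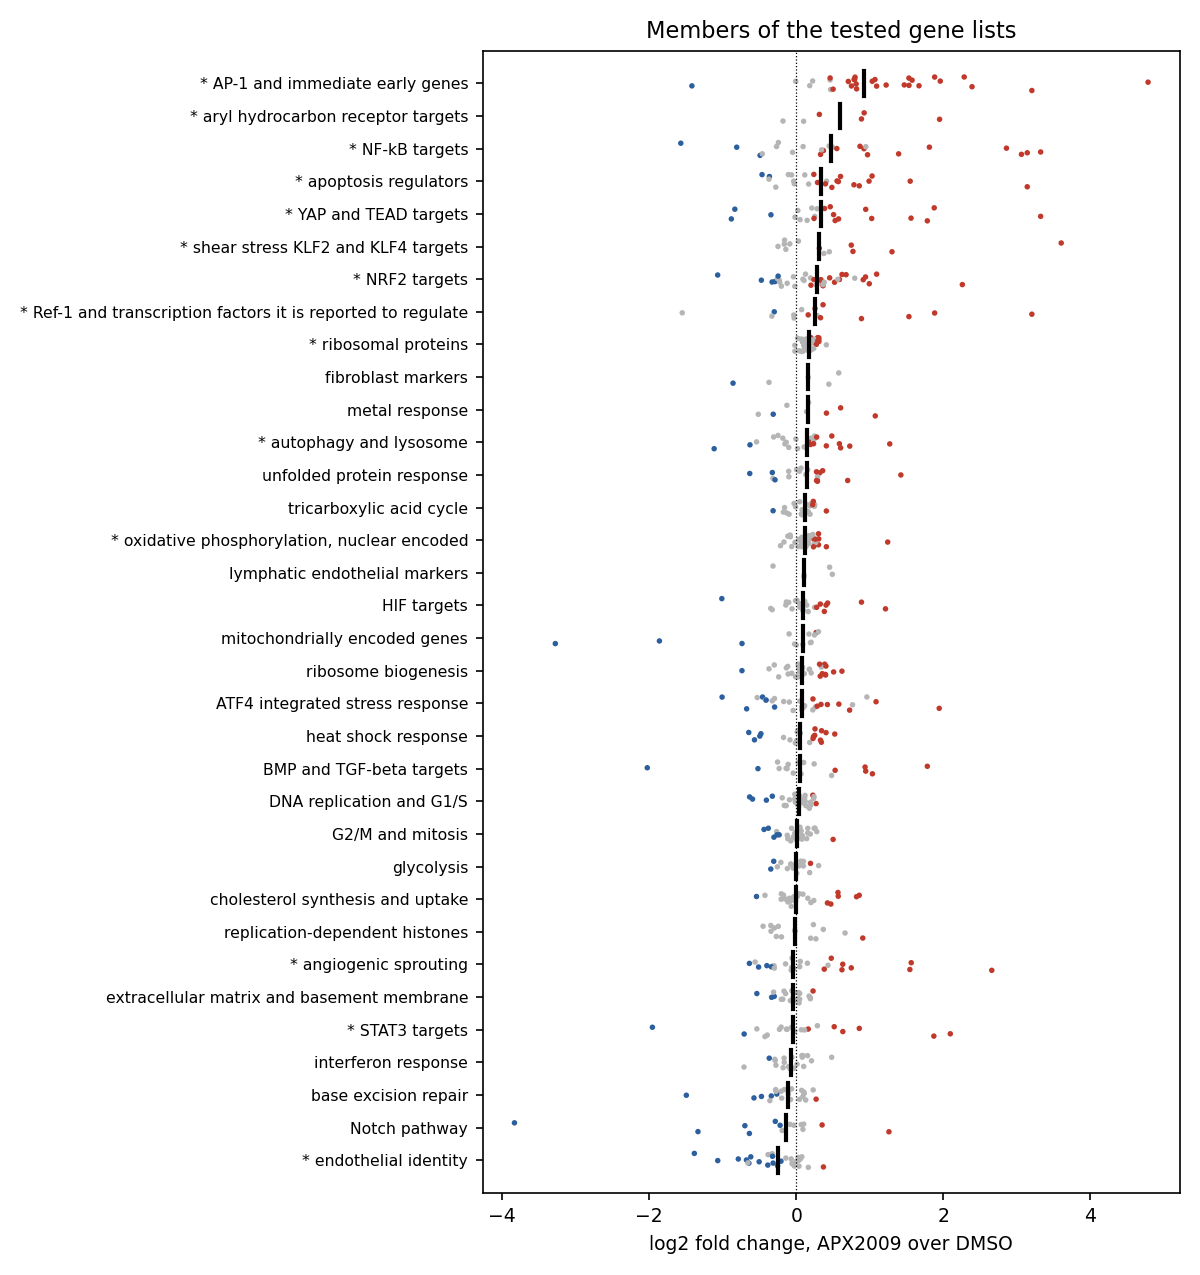
Each point is a tested member of a gene list, placed by its log2 fold change (APX2009 over DMSO) on the x axis, red or blue where it rose or fell with an adjusted p under 0.05 and grey otherwise; the black bar is the list's median and an asterisk marks a list called by camera, and 1 of the 35 tested lists is not drawn. The AP-1 and immediate early genes have the highest median, 0.93, and endothelial identity the lowest, -0.25.

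Mitochondrially encoded genes did not move together. MT-ND6, the 1 respiratory chain gene on the light strand, was 9.69-fold lower, from 462 ± 77.1 CPM with DMSO to 47.8 ± 15.3 CPM with APX2009 (log2 fold change -3.28 ± 0.20 SE, edgeR adjusted p = 4.61e-08). It lies on chromosome M from 14149 to 14673 (− strand). MT-ND5 on the opposite strand was 3.63-fold lower and MT-ND3 1.67-fold lower. Of 13 tested members 3 fell, 1 rose and 9 did not pass, over all genes and adjusted over the list alone. The list's mean log2 fold change was -0.35 and its median 0.09. It was not called (camera adjusted p = 0.0755), but was with the replicate block (adjusted p = 0.00258). It was also called on leaving out DMSO replicate 3 (0.0425), DMSO replicate 4 (0.0347), APX2009 replicate 1 (0.0143) or APX2009 replicate 2 (0.0269). Transfer RNA genes MT-TY, MT-TE, MT-TQ and MT-TP, all on the light strand, were 50.6-fold, 44.0-fold, 30.3-fold and 16.5-fold lower, and MT-TS1 was 4.84-fold lower. Those other than MT-TS1 had 6.69 to 11.3 CPM with DMSO but 0.130 to 0.512 CPM with APX2009, so their folds rest on few counts. As polyadenylated RNA was captured, the counts need not measure all RNA of these genes. The share of all mitochondrial genes in the counts was 7.12% ± 0.834 with DMSO and 6.32% ± 0.822 with APX2009 (SD, n = 5, exact permutation p = 0.183), and was lower with APX2009 in all 5 pairs of the same replicate number (paired t test, adjusted p = 0.00891; exact sign-flip p = 0.0625, the smallest possible). Mitochondrial genes have near-identical nuclear copies, so their counts are uncertain where reads could be split.

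**Figure D4:**
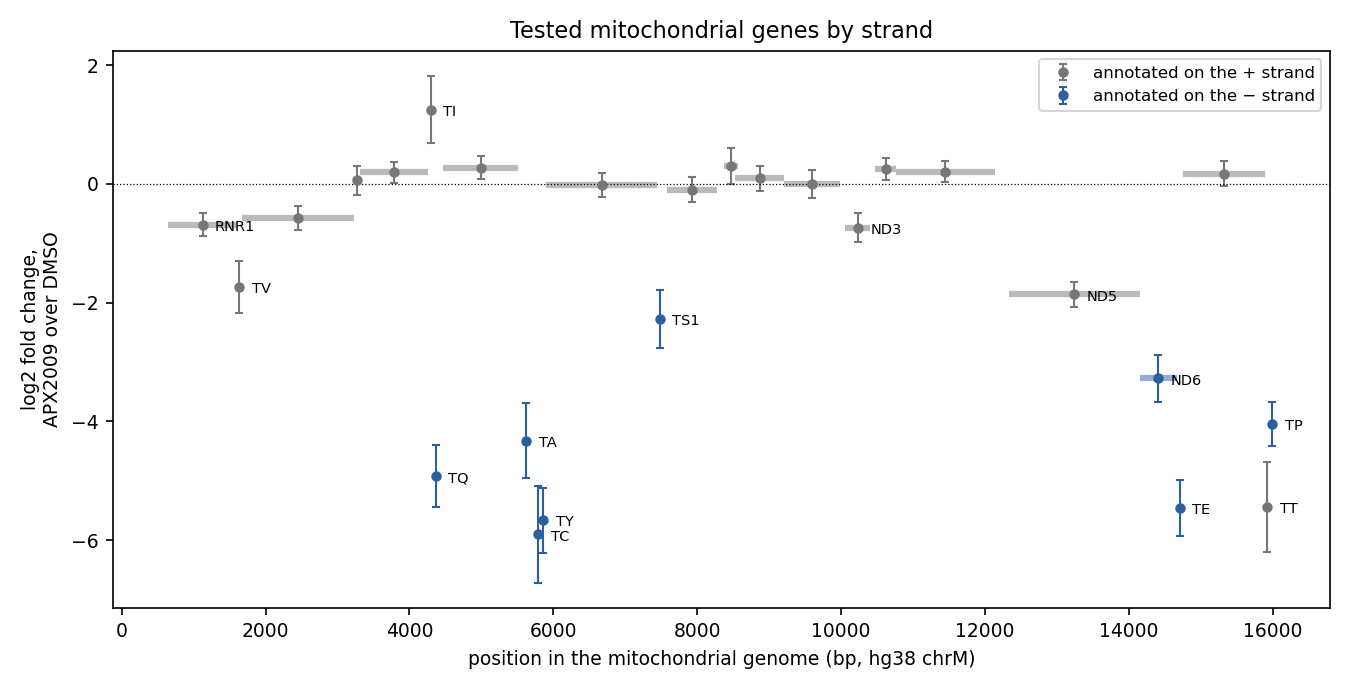
Each point is a tested mitochondrial gene at its position (x axis, bp on chrM of hg38) with its log2 fold change (APX2009 over DMSO, y axis) and a bar of 2 standard errors each way; thick lines span the genes. Genes annotated on the − strand (blue) are all below 0, with MT-ND6 at -3.28, while most on the + strand (grey) lie near 0, with MT-TT, MT-ND5 and MT-TV lower.

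The 19 other tested lists, lymphatic and fibroblast markers included, were not called. The HIF targets had 7 members up and 1 down of 24, with BHLHE40 2.32-fold and the histone demethylase KDM3A 1.85-fold higher, and a camera adjusted p of 0.0684. This became 0.0474 with the replicate block, 0.0384 without DMSO replicate 5, 0.0442 without APX2009 replicate 1 and 0.0410 without APX2009 replicate 4. The BMP and TGF-beta targets had 5 up and 2 down of 18 (adjusted p = 0.0805, and 0.0380 with the block), and SMAD6, an inhibitor of BMP signalling, was 4.07-fold lower. ATF4 targets had 8 up and 5 down of 29 (adjusted p = 0.0974, and 0.0461 with the block), with PPP1R15A up 3.85-fold. Ribosome biogenesis had 9 up and 1 down of 30 (adjusted p = 0.0989, and 0.0439 to 0.0477 without DMSO replicate 3, DMSO replicate 4 or APX2009 replicate 2). The unfolded protein response had 8 up and 3 down of 20 (adjusted p = 0.103), with the chaperone DNAJB9 up 2.68-fold. Base excision repair, the pathway of APEX1, had 1 up and 5 down of 23 (adjusted p = 0.154), and the glycosylase NEIL3 was 2.82-fold lower. The Notch pathway had 2 up and 6 down of 14 (adjusted p = 0.168), with NRARP 2.52-fold and LFNG 14.2-fold lower and HES1 2.40-fold higher. LFNG was rare, at 1.42 ± 0.453 CPM with DMSO and 0.0970 ± 0.0615 CPM with APX2009, so its fold rests on few counts. The tricarboxylic acid cycle had 3 up and 1 down of 24 (0.155), the metal response 3 and 1 of 8 (0.206), cholesterol synthesis and uptake 6 and 1 of 25 (0.206), and the heat shock response 9 and 4 of 21 (0.252). Cell cycle lists gave 2 up and 4 down of 32 for DNA replication and G1/S (0.841) and 1 and 5 of 28 for G2/M and mitosis (0.935), both with a median above 0 and a mean below. Extracellular matrix and basement membrane had 1 and 3 of 22 (0.711), the interferon response 0 and 1 of 20 (0.711), glycolysis 1 and 2 of 19 (0.935) and replication-dependent histones 1 and 0 of 15 (0.896). With the block ISG15 of the interferon list passed as lower (adjusted p = 0.0371) and HIST1H1C of the histone list as higher (0.00982). OAS1, the 1 called interferon gene, lost its call without DMSO replicate 3 or APX2009 replicate 2 or 5 (0.0639 to 0.0803). HIST1H4C, the 1 called histone gene, lost it without a low-count filter (0.0795) and without DMSO replicate 2 or APX2009 replicate 3 or 5 (0.05005 to 0.0627). With fry 8 of the uncalled lists were called, the HIF, BMP and TGF-beta, ATF4, unfolded protein response, base excision repair, tricarboxylic acid cycle, Notch and metal response lists (adjusted p of 6.51e-05 to 0.0243). The counts of these lists adjusted over the list alone differed from those over all genes by at most 2 members in either direction. The median was below 0 and the mean above for the cholesterol and histone lists, which camera placed as higher. Without a low-count filter 8 of the uncalled lists were called, the HIF, BMP and TGF-beta, ATF4, unfolded protein response, ribosome biogenesis, base excision repair, Notch and mitochondrially encoded lists.

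Markers of other cell types were mostly near 0. Lymphatic endothelial markers had 0 of 5 tested members changed (camera adjusted p = 0.711), but with the replicate block PROX1 and RELN passed as higher (adjusted p of 0.0149 and 0.0166) and FLT4 as lower (0.0246). Other alternatives also gave calls. PROX1 passed with DESeq2 (0.0303) and with median-ratio factors (0.0461), among others. FLT4 and RELN passed without DMSO replicate 5 (0.00439 and 0.0172), among others. LYVE1 reached 51.9 CPM and FLT4 31.9 CPM in 1 library. Fibroblast markers had 0 up and 1 down of 5 (adjusted p = 0.968). The 1, TWIST2 (edgeR adjusted p = 0.0411), lost its call with limma-voom (0.0906) and on leaving out any 1 library other than DMSO replicate 5 or APX2009 replicate 4 (0.0552 to 0.114). Their most abundant member, COL1A2, reached 8.08 CPM. POSTN passed as higher with the block (0.0370), and FAP passed as higher without DMSO replicate 5 (0.0378). Too few markers were detected to test 5 lists. Of 13 pericyte and smooth muscle markers 4 were tested and 0 changed, though RGS5 and TAGLN passed as higher with the block (adjusted p of 0.00215 and 0.0318). RGS5 was abundant in both groups, up to 1567 CPM, and ANPEP reached 850 CPM in 1 library, while PDGFRB had 5 counts over all 10 libraries. Of 11 Mueller glia and astrocyte markers 2 were tested. VIM, which endothelial cells also make, reached 6121 CPM and passed only with the block (adjusted p = 0.0212), and GLUL rose from 187 ± 6.91 to 230 ± 10.9 CPM (edgeR adjusted p = 0.00185), while AQP4 had no count. Of 11 leukocyte markers 3 were tested, with LAPTM5 at up to 69.1 CPM and CORO1A lower (edgeR adjusted p = 0.0285, 3.72 ± 0.563 and 2.56 ± 0.551 CPM). PTPRC had 4 counts. Of 12 pigment epithelium markers 2 were tested, led by BEST1 at up to 17.7 CPM, and of 12 retinal neuron markers 1, TUBB3, at up to 2.11 CPM, and 0 of these changed.

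Composition moved with treatment in 3 of 8 measures per library by exact permutation tests. A paired t test by replicate number, chosen after these values were seen, called 5, but it changes both the pairing and the kind of test; the exact sign-flip test of the pairs called 0, with p = 0.0625 for each of these 5, the smallest that 5 pairs can give. Long noncoding RNA genes took 1.11% ± 0.208 of the counts with APX2009 and 0.790% ± 0.0897 with DMSO, ribosomal RNA genes, mitochondrial ones included, 0.609% ± 0.0736 and 0.981% ± 0.129, and genes on alternative sequences 0.0755% ± 0.000935 and 0.0828% ± 0.00263 (SD, n = 5). For each the exact permutation p was 0.00794, the smallest that 5 against 5 can give, and the adjusted p was 0.0212. The mitochondrial genes MT-RNR1 and MT-RNR2 made up most of the ribosomal RNA share. They had 1129 and 8333 CPM with DMSO and 701 and 5615 CPM with APX2009. NEAT1 made up 4.81% to 9.05% of the long noncoding counts with APX2009 and 1.01% to 2.34% with DMSO. Without it the shares were 1.03% ± 0.173 and 0.776% ± 0.0834 and the groups overlapped (exact permutation p = 0.0159). The share without it was still higher with APX2009 in all 5 pairs of the same replicate number. The paired test also called the mitochondrial share, given above, and the share in the 10 most abundant genes, 7.86% ± 0.506 and 8.27% ± 0.623 (adjusted p = 0.00891, lower with APX2009 in all 5 pairs). The deposited column names number the DMSO libraries in one unbroken run and the APX2009 libraries in another, so place on the sample sheet follows the groups; no batch is stated.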

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

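Among 246 groups of 5 values (123 named genes in both treatments), 13 had 1 library far from the others, the gap to its nearest neighbour being over 0.71 of the group's range on a log2 scale. Chance alone gives about 12.3. Of the 13, 7 were in DMSO replicate 5, which also stood apart from the other DMSO libraries on the third principal component.

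In DMSO replicate 5, VEGFC was at 121 CPM against 99.9 to 102 CPM in the others (gap 0.911 of the range) and ANGPT2 at 125 CPM against 80.5 to 90.9 (0.723), both toward the values with APX2009 (162 ± 14.2 and 158 ± 15.7 CPM, SD, n = 5). Also toward APX2009, but far from it, 3 mitochondrial transfer RNA genes were lowest there: MT-TE at 6.81 CPM against 8.81 to 9.74 (0.718), MT-TQ at 7.48 against 11.2 to 13.2 (0.719) and MT-TS1 at 5.12 against 9.09 to 11.3 (0.723). RPL22 was lowest there at 78.7 CPM against 85.5 to 87.2 (0.810), away from APX2009, and TWIST2 at 0.961 CPM against 2.55 to 3.60 (0.733).

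The other values were scattered over libraries. IRS2 was lowest in DMSO replicate 4, at 0.720 CPM against 1.34 to 1.62 (0.762), and SLC2A3 in DMSO replicate 3, at 61.7 against 64.5 to 65.6 (0.730). With APX2009, CCN2 was lowest in replicate 4, at 2821 CPM against 3182 to 3272 (0.812), SLC30A1 in replicate 1, at 22.1 against 30.7 to 34.7 (0.725), RPL22 highest in replicate 2, at 110.4 against 99.3 to 100.4 (0.894), and FAP highest in replicate 5, at 2.80 against 0.581 to 0.862 (0.762). Without DMSO replicate 5 the number of called genes was 5732 against 4671 with all libraries.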

How the results depend on the processing

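Of 123 named genes 22, and of 35 gene lists 21, changed their side of the threshold under at least 1 of the alternatives run on them. The others kept it wherever they were tested, and 0 reversed. Some genes and lists were not tested under every alternative, as with the stricter low-count filter. The stricter thresholds were applied only to the number of called genes. The number of called genes stayed within 1.5 times of 4671 under other scaling factors, other low-count filters, DESeq2 (5206 calls) and limma-voom (4703), and all calls shared with those fits had the same direction. At an adjusted p under 0.01, 2832 genes were called, 1300 higher and 1532 lower, and with a change of at least 2-fold, 830, of which 282 were higher and 548 lower. These are stricter thresholds on the same fit. With library size alone 1355 genes were higher, because that scaling shifts all fold changes down (median log2 fold change -0.11 against -0.01); the share of called genes that were higher was 26.9%, against 33.3% with upper-quartile factors, 50.5% with median-ratio factors and 46.2% with TMM. Without a low-count filter 23 lists were called and with an estimated correlation 4, against 15; the cause of neither change was tested. With the replicate number as a block 6509 genes were called, 3284 of them higher against 2158 without it, and 19 lists. Of the 123 named genes the block changed the call of 7, all to called (HIF1A, PROX1, ISG15, HIST1H1C, FLT4, RELN and POSTN), and of the lists 4 (HIF, BMP and TGF-beta, ATF4 and the mitochondrially encoded genes). Of the cell type markers given beside these 123 genes it also called RGS5, TAGLN and VIM. Leaving ANPEP aside, it changed no other call of a gene or list named here. A paired t test by replicate block, added after the values were seen, called 5 of the 8 measures per library, against 3 by unpaired exact permutation tests, so both the pairing and the test differ; an exact sign-flip test of the pairs gave p = 0.0625 for each of the 5, the smallest possible, and called 0. Only 3 of the 5 DMSO and 2 of the 5 APX2009 libraries correlated best with their own number. Leaving out 1 library gave 3728 (without APX2009 replicate 3) to 5732 (without DMSO replicate 5) called genes, 1691 to 2732 of them higher and 2037 to 3000 lower, and 13 to 17 called lists. In the simulated data 64.2% of genes changed 1.5-fold were called. Far fewer genes were changed there than were called in the real data, so the share found in the real data may differ. An adjusted p of DESeq2 was not available for 13042 genes, which are not counted.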

Other observations

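The tests of mitochondrial RNA as a whole, the strand groups themselves and the zinc finger set were chosen after the fold changes had been seen, and so were a narrower set of antisense genes and the test of zinc finger genes against DNA level; the bounds for the other tests were written before their results. All 8 tested mitochondrial genes on the light strand, MT-ND6 and 7 transfer RNA genes, were lower with APX2009, with log2 fold changes from -5.90 to -2.28 and a median of -4.62. The 12 heavy-strand messenger RNA genes had a median of 0.13, with MT-ND5 and MT-ND3 lower and MT-ND2 higher. Light-strand genes made up 0.742% ± 0.0515 of the mitochondrial counts with DMSO and 0.0767% ± 0.0168 with APX2009 (SD, n = 5), with no overlap between the libraries of the groups (exact permutation p = 0.00794, the smallest possible). This share mostly restates MT-ND6, which had 462 CPM with DMSO, against 2.40 to 11.3 CPM for each of the 7 transfer RNA genes. On the other strand, transfer RNA gene MT-TT was 43.4-fold lower, from 2.39 CPM with DMSO to 0.0537 CPM with APX2009, and MT-TV 3.34-fold. The ribosomal RNA genes MT-RNR1 and MT-RNR2 were 1.61-fold and 1.48-fold lower, and MT-TI was higher (log2 fold change 1.25). The medians of the light-strand genes were -4.73 to -4.61 under all 4 scalings tried.

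For this pattern, a fall of mitochondrial RNA as a whole is argued against by the heavy-strand messenger RNA median of 0.13, since that would need -1 or less. Its 95% bootstrap interval over genes (-0.06 to 0.23) does not measure the spread between libraries. It also takes genes as independent, while the mitochondrially encoded list had an estimated correlation of 0.869. The bound was set after the fold changes were seen. The set leaves out the heavy-strand ribosomal and transfer RNA genes, several of which were lower. Poorer strand separation with DMSO would have needed antisense counts at least 4 times higher there relative to the genes they overlap. A narrower set was computed first, 105 genes at 1% or less of their partner's density. Its ratio was 1.44 (exact permutation p = 0.0238), with up to 2.20 in 1 pair of libraries. That passed the bound of 2, written for the wider set below, so the narrower set did not decide. The test was then run on all 187 nuclear genes wholly antisense to expressed exons. There the ratio was 1.22 (exact permutation p = 0.143) and 0.674 to 1.87 over pairs of libraries, under the bound. With DMSO the antisense counts were 0.301% of their partners' in this wider set and 0.0415% in the narrower one. The wider set may thus hold mostly antisense transcription itself, which would mask a change in strand separation. In neither set did a pair reach 4, but the part due to strand separation was not measured, so this explanation is not excluded. Whether the 1.44 comes from strand separation or from antisense transcription itself was not tested. It is smaller than the fall of the light-strand genes. Residual nuclear DNA is argued against by 380 olfactory receptor genes, whose summed CPM was 1.02 times higher with DMSO (interval 0.829 to 1.34), though they rest on 549 counts in all. As nuclear genes they do not measure residual mitochondrial DNA, which was not tested. A candidate explanation, which was not tested, is that APX2009 lowers transcription of the light strand or speeds the decay of its RNA. These counts cannot separate the lowered transcription from the faster decay. Neither would by itself cover the heavy-strand genes MT-TT, MT-ND5 and MT-TV, which were also lower. The libraries captured polyadenylated RNA, so the counts need not measure all RNA of these genes.

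Genes named as zinc fingers (ZNF, ZSCAN, ZKSCAN and ZFP with a number), mostly DNA-binding repressors, tended to be lower with APX2009. Of 460 tested 196 fell and 43 rose (42.6% fell, against 17.4% of 11462 other protein-coding genes), with a median log2 fold change of -0.35. ZSCAN32, ZNF112 and ZNF45 had log2 fold changes of -1.99, -1.92 and -1.46, beside ZNF552 at -2.18. The median was -0.46 to -0.33 under the 4 scalings. Camera gave p = 6.74e-08 with the preset correlation, but p = 0.0580 with an estimated one, so the set may not stand apart from other genes by that test.

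After a smooth trend in length, GC content and mean expression fitted on the other protein-coding genes was removed, the zinc finger median was -0.21 (95% bootstrap interval -0.29 to -0.13), beyond the bound of -0.1, so that trend does not account for all of it. It accounts for part: removing mean expression alone moved the median from -0.35, relative to the other genes, to -0.18 (interval -0.25 to -0.10). Residual DNA as the source of the fall is argued against by its level. At the density of olfactory receptor counts with DMSO (0.00186 CPM per kb, upper end of the interval 0.00321) DNA would give a zinc finger gene a median of 0.0177 CPM, while the genes fell by a median of 0.745 CPM; less that DNA level the median fall was 0.721 CPM (interval 0.534 to 1.03). A bound on the ratio of 1.02 itself, written before, did not decide, as its interval reaches past the median fold of 1.28 of the zinc finger genes. What lowers them was not tested.

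Chance was tested by 100 of the 126 splits of the 10 libraries into 5 and 5. For the number of called genes 1 of the 100, the real split, gave as many. The real value was 4671 and the highest other 566, so chance is excluded at 0.05 over these splits. That other split put replicates 1 to 3 of DMSO with replicates 1 and 2 of APX2009 and so follows the structure of the replicate numbers. For the number of called lists 3 of the 100 gave as many, the real one with 15 and others with up to 18. Over these 100 splits, which ignore the replicate numbers, chance is excluded at 0.05 for the number of lists. Yet 2 of the other splits called more lists than the real one did. The 99 other splits called a median of 7 lists (quartiles 5 and 10). Each of them has unequal numbers of DMSO libraries on its sides and so keeps part of the treatment difference. These calls thus do not give camera's rate of false calls. With an estimated correlation only 4 lists were called, so 1 list called by camera is weak evidence by itself. Of the other splits, 12 part all 5 pairs of replicate numbers as the real one does. They called 0 genes each with edgeR and at most 12 lists, while the 87 that part fewer pairs called up to 566 genes and 18 lists. Among splits that part all 5 pairs the real one was highest for genes and lists. Such splits are too few to give a share under 0.05, so with the pairing kept chance is not excluded at that level.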
